A study of Homo sapiens with 8 samples.

How the data were processed

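RNA from H1 human embryonic stem cells sorted into a large and a small fraction was measured on 8 arrays, 4 per fraction, of the Affymetrix U133 Plus 2.0 design for human transcripts. Per the labels' protocols, biotin-labelled cRNA was made from 1 ug of total RNA with a 3 prime amplification kit, and 15 ug were hybridised for 16 hours. Per the series design text, the scans were read with GeneChip Operating Software and imported into Rosetta Resolver (version 7.1), where the authors combined replicates for their own ratios. The deposited value table holds a linear intensity per probe set and array, with 1 column per array and no header that gives its background correction or scaling. Which program wrote these intensities is not given in the sources used here. The deposited intensities were not on a common scale, since the log2 75th percentiles of the arrays spanned 1.33.

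Groups and replicate numbers were taken from the sample titles. Per the labels, the 4 sorts of a group were biological repeats. The sources used here do not say whether equally numbered small and large sorts shared a culture or a day, so no pairing entered the main comparison. Scan dates were not used here.

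Intensities were moved to the log2 scale after adding a pseudocount of 1.813, the 10th percentile of all values, so a fold change of a dim gene is understated. Quantile normalization between arrays was applied because the span of the 75th percentiles exceeded 0.2, a rule set before the data were examined. The 62 control probe sets were left out, and probe sets were tested if their mean over the 8 arrays exceeded the 40th percentile (3.623 on the log2 scale), which left 32768. GEO's platform annotation gave 41091 probe sets 1 gene symbol, 1801 several and 11721 none, and 41037 of the first kind were found by gene ID in a reference table used to update symbols. Probe sets with several symbols named no gene. Each gene was represented by the tested probe set with the highest mean over all arrays, which gave 14726 genes. Affymetrix probe sets ending in _x_at or _s_at can bind several transcripts.

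Small and large cells were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), small minus large, two-sided, with Benjamini-Hochberg adjustment over probe sets and again over genes and a threshold of 0.05. Errors printed beside log2 differences are moderated standard errors, with 4 arrays per group. The precision of each value is limited by the number of arrays: the median standard error over genes was 0.24. Quality measures were compared with an exact permutation test over 70 assignments, whose smallest two-sided p is 0.0286.

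The 44 gene lists were fixed before the data were examined and tested with camera (preset correlation 0.01), with an estimated correlation beside it, and with fry. Shifts of lists are relative to the median of all genes, which was 0.05 in the main setting, -0.05 on the deposited scaling, 0.10 with median centring and 0.09 with 75th percentile scaling. The choice to give camera the same variance trend as the gene tests was made after output without it had been seen. Without the trend 6 lists passed, and the p53 target list had an adjusted p of 0.0522, so its call rests on that choice.

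Named genes were chosen by a rule set before the data were examined. It took the 10 called genes with the largest difference in each direction whose small and large values did not overlap. From each list it took up to 4 called members with the largest difference, or, where none was called, up to 2 members with the smallest p. NANOG, SOX2 and POU5F1 were to be given in any case. The rule named 97 genes, of which 47 were called.

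Simulated data with the spread of the real genes were used to test the procedure. Among 14726 simulated genes, 2 of 67 genes changed by 0.58 on the log2 scale were called, 23 of 67 changed by 1 and 39 of 66 changed by 1.5, with 3 unchanged genes called. In a second simulation the list shifted by -0.5 was called and 0 of the others were. Noise was drawn independently for each gene, so correlation between genes was left out. In the real lists the estimated correlation reached 0.344, so this simulation does not show how often camera calls unshifted lists in these data.

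Beside the leaving out of each of the 8 arrays in turn, 16 alternatives were chosen before the data were examined: the deposited scaling, median centring, 2 other pseudocounts, 2 other filters, a replicate block, a fit without the variance trend, a robust fit, array weights, fewer or averaged probe sets, 2 thresholds, an estimated correlation and fry. Another 6 were chosen after: scaling to the 75th percentile or to a trimmed mean, cyclic loess, array brightness or the 3 prime to 5 prime difference as a covariate, and 2 arrays left out. Named genes were also refitted after that point without _x_at and _s_at probe sets, a setting planned for counts and lists. The 14 lists of gene families in the closing section were also chosen after the data were examined. Arrays were normalized together before any was left out.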

Results

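The RNA came from H1, an established human embryonic stem cell line, grown over irradiated mouse embryonic fibroblasts and separated on a flow cytometer by forward and side scatter, which change with cell size and internal granularity. A large and a small fraction were each collected in 4 sorts that the submitters describe as independent, and each sort was hybridised to its own 1-colour Affymetrix expression array. This gave 4 small and 4 large arrays of 54675 probe sets, 62 of which were controls. The 75th percentile of the deposited intensities ran from 41.9 to 106 units, a 2.52-fold range. On the log2 scale it was 5.93 ± 0.53 (SD, n = 4) in small and 6.08 ± 0.57 (SD, n = 4) in large cells, a difference within the spread between sorts (exact two-sided permutation p = 0.714). The number of arrays limits the precision of every value below.

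The comparison asked which transcripts distinguish the small from the large stem cells. Each array took the same amount of labelled RNA, and the arrays were normalized to each other. The values are therefore levels relative to the RNA measured and not amounts per cell, also where lower or higher in small cells is written. Over the lists of embryonic stem cell surface and secreted proteins, the unfolded protein response, epithelial junctions and the lysosome, 26 of 85 tested genes were lower in small cells and 0 higher, while the pluripotency factors NANOG and SOX2 did not pass the test. As lists these 4 passed with a preset correlation between genes, but adjusted p was 0.0569, 0.0508, 0.0787 and 0.0569 with an estimated correlation. The amino acid transporter SLC7A3 was 2.96-fold lower in small cells (log2 difference -1.56 ± 0.21 SE, n = 4 per group, adjusted p = 0.00651), and the desmosomal cadherin DSG2 was 2.86-fold lower (-1.52 ± 0.19 SE, adjusted p = 0.00651). The calcium-binding protein gene S100A6 was 3.22-fold higher (1.69 ± 0.25 SE, adjusted p = 0.00754) and HINT3, which encodes a histidine triad protein, was 2.46-fold higher (1.30 ± 0.19 SE, adjusted p = 0.00754). NANOG was at 10.67 ± 0.08 (SD) in small and 10.73 ± 0.07 (SD) in large cells, a log2 difference of -0.05 ± 0.10 SE (adjusted p = 0.847). SOX2 had a difference of -0.17 ± 0.12 SE (adjusted p = 0.505), and POU5F1 was not analysed here because no tested probe set was assigned to it alone.

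Of 14726 genes tested, 293 differed at an adjusted p under 0.05, 44 of them higher and 249 (85.0%) lower in small cells, and 101 differed by at least 2-fold, 7 higher and 94 lower. At the level of probe sets, 491 of 32768 differed, 65 higher and 426 lower. The 4 small and 4 large values did not overlap for 1474 genes, or 10% of those tested, where chance gives 2.86%. At an unadjusted p under 0.05 there were 2431 genes, and 48.5% of these were lower, a share that was 82.4% on the deposited scaling and 38.0% with scaling to the 75th percentile. That last scaling called 62 genes higher and 148 lower. The number of called genes was not stable: limma called 0 genes on the deposited scaling, with median centring and without a variance trend (494, 1575 and 2234 genes at an unadjusted p under 0.05), and from 62 (without small array 1) to 555 (without large array 1) when 1 array was left out. Without small array 1, 2 genes were higher and 60 lower (96.8%), and without large array 1, 196 were higher and 359 lower (64.7%). The variance trend and the rule that led to quantile normalization were fixed before the data were examined.

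**Figure D1:**
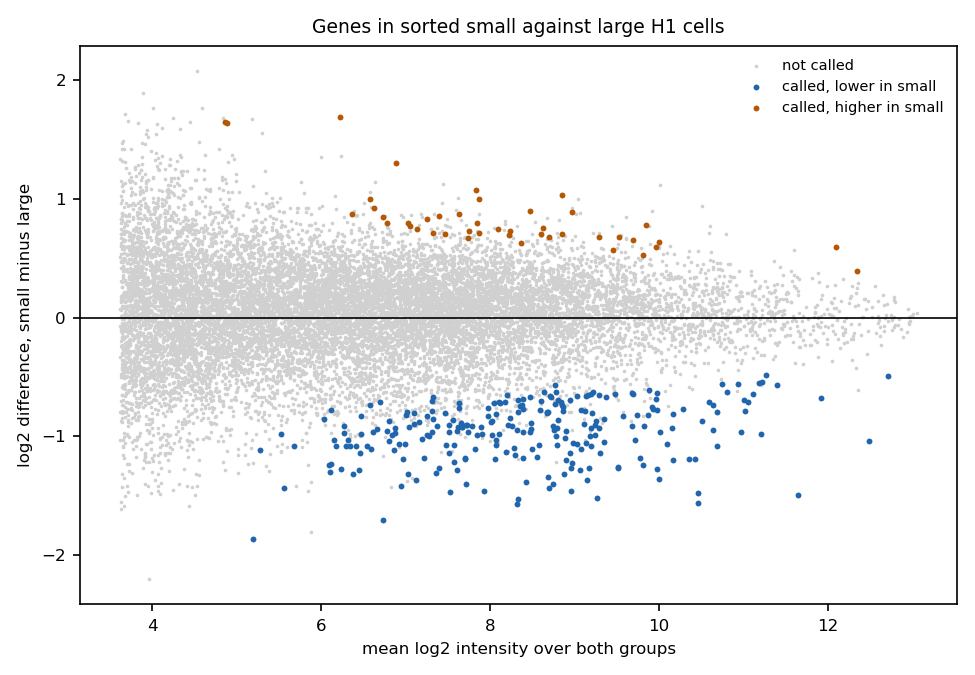
Each point is 1 of 14726 genes, with the mean log2 intensity over both groups on the horizontal axis and the log2 difference, small minus large, on the vertical axis. The 249 genes called lower (blue) outnumber the 44 called higher (orange).

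Among the 10 genes called with the largest differences downward were genes of other membrane and matrix proteins: FREM2, an extracellular matrix protein gene (-1.71 ± 0.26 SE), the zinc transporter gene SLC39A10 (-1.48 ± 0.21), the mannose 6-phosphate receptor gene IGF2R (-1.47 ± 0.27) and the VEGF receptor gene KDR (-1.46 ± 0.29). CCDC47, a membrane protein of the endoplasmic reticulum, differed by -1.57 ± 0.19 and LEMD3, of the inner nuclear membrane, by -1.53 ± 0.23. The noncoding RNA KCNQ1OT1 had a difference of -1.87 ± 0.41 and the mitochondrially encoded ND2 of -1.49 ± 0.24. With 1 array left out, KCNQ1OT1 ran from -2.16 to -1.37 and kept its call in 3 of 8 fits. The 10 called genes with the largest differences upward, S100A6 and HINT3 aside, were BCL7C (1.64 ± 0.36), AIF1 (1.64 ± 0.38), COMMD1 (1.08 ± 0.22), SEC62 (1.03 ± 0.22), GLRX (1.00 ± 0.21), SWI5 (1.00 ± 0.22), GADD45GIP1 (0.93 ± 0.22) and PSMG4 (0.90 ± 0.19). Probe sets disagreed for some of these: for SEC62, 1 of 4 tested probe sets was higher, and the mean of its probe sets was -0.04. Without probe sets ending in _x_at or _s_at, a check of named genes added after the data were examined, SEC62 was at -0.43 and PSMG4 at -0.46, and neither passed. AIF1 was higher on 2 of 3 probe sets, and GADD45GIP1 and PSMG4 each on 1 of 2. Of 192 called genes with several tested probe sets, 51 had another probe set of opposite sign. Of 47 named genes called, 14 kept the call with each array left out in turn, among them SLC7A3, DSG2, FREM2, CCDC47, LEMD3, ND2, SLC39A10, S100A6 and HINT3. A single array stood apart from the others of its group for AIF1, SEC62, GLRX, CCDC47, PDIA3, CTSD, GRN, CTSL, XIAP, CCN2 and NODAL.

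The list of surface and secreted proteins of embryonic stem cells was the most shifted, with a median log2 difference of -0.83 relative to all genes. Of its 20 tested genes, 12 were lower and none higher, and 15 were lower when adjusted over the list alone. Its members include the stem cell factor receptor KIT (-1.40 ± 0.24 SE, adjusted p = 0.0123), the tetraspanin CD9 (-1.26 ± 0.22, adjusted p = 0.0149) and the WNT receptor FZD7 (-1.25 ± 0.24, adjusted p = 0.0214). The unfolded protein response list had a median of -0.57. Of its 22 genes, 5 were lower, and 13 when adjusted over the list alone. The chaperones of the endoplasmic reticulum in it included PDIA3 (-1.20 ± 0.16, adjusted p = 0.00651), HSPA5 (-1.06 ± 0.21, adjusted p = 0.0233), PDIA4 (-0.90 ± 0.18, adjusted p = 0.023) and CANX (-0.87 ± 0.16, adjusted p = 0.0171). The epithelial junction list had a median of -0.56, with 5 of 22 genes lower, and 10 lower and 1 higher when adjusted over the list alone. E-cadherin, CDH1, differed by -1.19 ± 0.24 (adjusted p = 0.0262), occludin, OCLN, by -1.08 ± 0.20 and P-cadherin, CDH3, by -0.79 ± 0.16. The lysosome and autophagy list had a median of -0.40, with 6 of 23 genes lower, and 10 lower and 1 higher when adjusted over the list alone. The saposin precursor PSAP differed by -1.28 ± 0.20 (adjusted p = 0.00754), progranulin, GRN, by -0.90 ± 0.21 (adjusted p = 0.0405) and the proteases CTSD by -1.11 ± 0.27 (adjusted p = 0.0495) and CTSL by -0.84 ± 0.19 (adjusted p = 0.0349). The median of this list was -0.61 without large array 1 and small array 3 and -0.27 with the mean of all probe sets of a gene.

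In camera, with a preset correlation between genes of 0.01, the adjusted p of these 4 lists was 2.28e-18, 4.21e-09, 1.65e-06 and 4.47e-06 in the order given. Adjusted p was 0.0569, 0.0508, 0.0787 and 0.0569 with an estimated correlation, so no list held its call there, while the rotation test fry, which asks whether the genes of a list move on balance in 1 direction, gave 0.00418, 0.00384, 0.0173 and 0.00418. The mean 3 prime to 5 prime log2 difference of GAPDH and ACTB is a sign of RNA quality. It was higher on all 4 small arrays than on large arrays 2 to 4. With it as a covariate the pooled median of the 4 lists was -0.61. Of 35 splits of the 8 arrays into 4 and 4, 12, the real one included, gave at least the 7 lists that passed camera here.

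**Figure D2:**
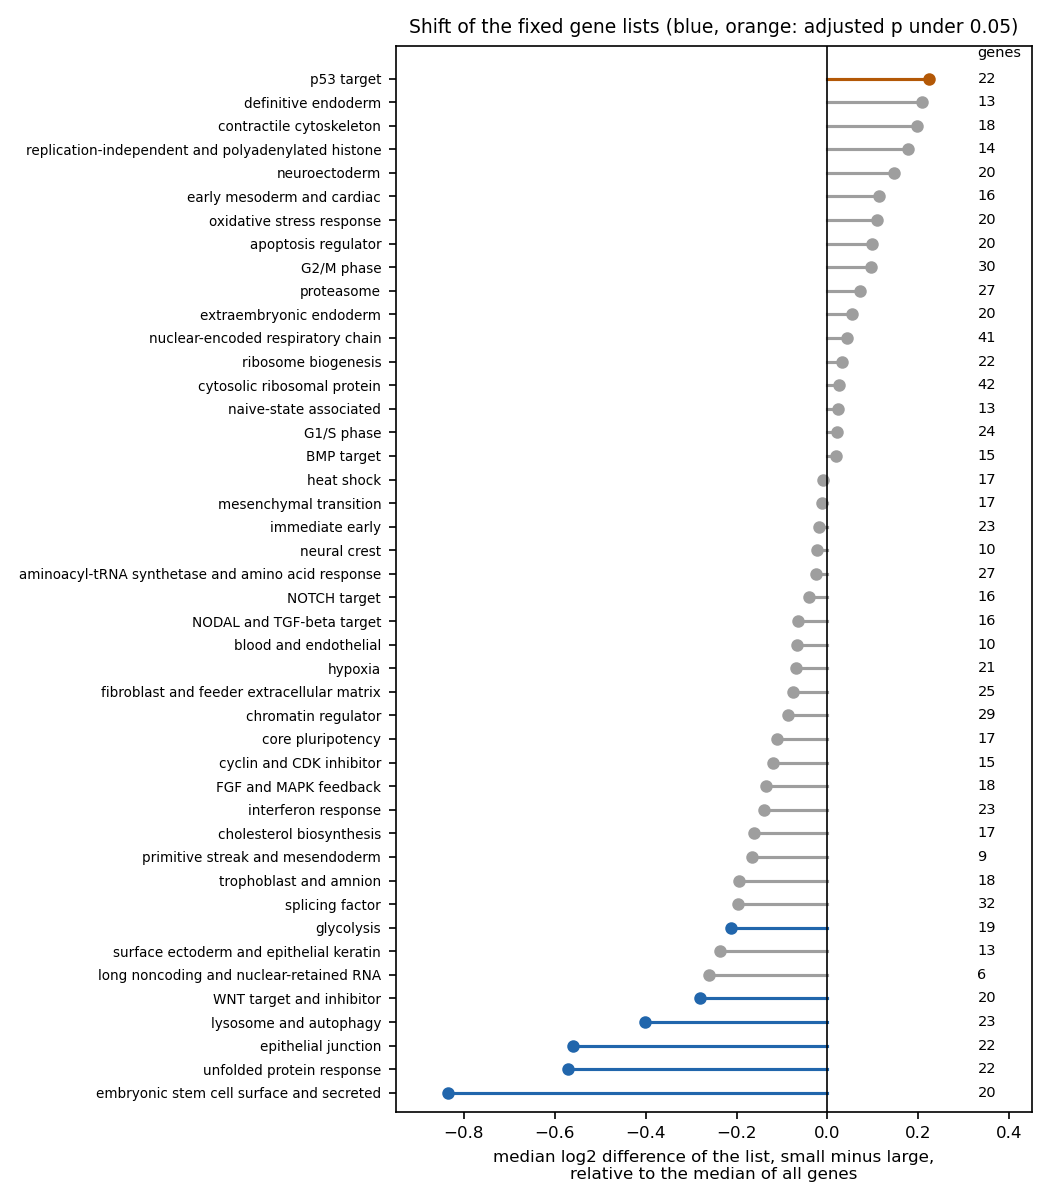
The horizontal axis is the median log2 difference, small minus large, of each of 44 gene lists relative to the median of all genes, with the number of tested genes on the right. The 7 lists in colour had a camera adjusted p under 0.05, and the surface and secreted list of embryonic stem cells lies lowest at -0.83.

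Another 3 lists passed camera with smaller shifts. The WNT target and inhibitor list had a median of -0.28 (adjusted p = 0.0054, and adjusted p = 0.235 with an estimated correlation), of -0.43 without large array 1 and of -0.49 without large array 1 and small array 3. Of its 20 genes, 2 were lower, FZD7 and the secreted WNT inhibitor SFRP2 (-0.82 ± 0.14 SE, adjusted p = 0.0106), and 3 when adjusted over the list alone. The glycolysis list had a median of -0.21 (adjusted p = 0.00563, and adjusted p = 0.437 with an estimated correlation), and 0 of its 19 genes passed alone, also when adjusted over the list alone. The glucose transporter SLC2A3 had a difference of -0.56 ± 0.17 and the enolase ENO1 of -0.26 ± 0.14, neither of which passed. The p53 target list had a median of 0.22 (adjusted p = 0.0419, and adjusted p = 0.412 with an estimated correlation), and 0 of 22 genes passed over all genes or when adjusted over the list alone. Its members with the smallest p were TNFRSF10B, a death receptor, at -0.49 ± 0.17, opposite to the list, and GDF15 at 0.64 ± 0.23. The p53 call was lost without large array 1 or 2 and without small array 1 or 3 (adjusted p = 0.103, 0.0734, 0.0854 and 0.0914, with a median of 0.12 without small array 1), and the glycolysis call without large array 2 (adjusted p = 0.095).

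Genes of pluripotency and of differentiated lineages did not pass as lists. For core pluripotency the median was -0.11 (adjusted p = 0.389), with 0 of 17 genes passing and 1 lower when adjusted over the list alone. FGF4 had a difference of -0.78 ± 0.20 (adjusted p = 0.0678) and GDF3 of -1.04 ± 0.45 (adjusted p = 0.26). The naive-state list had a median of 0.02 with 0 of 13 passing and 1 lower when adjusted over the list alone (adjusted p = 0.949). KLF4 was at 0.40 ± 0.19. Medians and adjusted p were 0.15 and 0.159 for neuroectoderm, -0.02 and 0.401 for neural crest, -0.17 and 0.695 for primitive streak and mesendoderm, 0.21 and 0.949 for definitive endoderm, and 0.11 and 0.582 for early mesoderm and cardiac genes. They were -0.19 and 0.453 for trophoblast and amnion, 0.05 and 0.395 for extraembryonic endoderm, -0.24 and 0.566 for surface ectoderm and keratins, and -0.07 and 0.49 for blood and endothelial genes. With 1 array left out, medians changed sign for the naive state, primitive streak (-0.268 to 0.05), neural crest (-0.222 to 0.142), extraembryonic endoderm (-0.123 to 0.267) and blood. Early mesoderm ran from 0.029 to 0.375, definitive endoderm from 0.09 to 0.269 and surface ectoderm from -0.241 to -0.045. Single members of these lists that were called were lower: LAMC1, a laminin chain (-1.31 ± 0.20, adjusted p = 0.00754), the glypican GPC4 (-0.93 ± 0.17, adjusted p = 0.0149), KIT, KDR and DSG2. The neural factor PAX6 had a difference of 1.77 ± 0.52 and STMN2 of 1.15 ± 0.48 with adjusted p = 0.106 and 0.247, and neither passed. PAX6 was at 5.63 on large array 1, within the 5.13 to 5.87 of the small arrays. On large arrays 2 to 4 it was between 2.74 and 3.24. EDNRB, ERBB3, IGFBP7, KRT18, SP5 and NODAL also did not pass. Adjusted over the list alone, 5 genes were lower for extraembryonic endoderm, 2 each for neural crest, definitive endoderm and surface ectoderm, and 1 for blood; early mesoderm had 1 higher and 1 lower, and neuroectoderm, primitive streak and trophoblast had 0.

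Markers of fibroblasts and feeder matrix split in direction, with a list median of -0.08 (adjusted p = 0.291). The feeders were mouse cells and the probe sets were designed for human transcripts, so this list does not test for feeder RNA. The median was 0.11 without large array 2 (adjusted p = 0.956), and the list passed without small array 2, at -0.20 (adjusted p = 0.0153). Of 25 genes, S100A6 was higher, and connective tissue growth factor CCN2 (-1.19 ± 0.19 SE, adjusted p = 0.00754) and the collagen COL6A1 (-0.95 ± 0.22, adjusted p = 0.0402) were lower. Adjusted over the list alone, 1 was higher and 4 lower. For COL6A1, 1 of 2 tested probe sets was lower, and without probe sets ending in _x_at or _s_at it was at 0.58 and did not pass. The mesenchymal transition list had a median of -0.01 (adjusted p = 0.956), with the integrin ITGB1 lower (-0.80 ± 0.17, adjusted p = 0.0332), and 3 genes higher and 3 lower when adjusted over the list alone. The contractile cytoskeleton list had a median of 0.20 (adjusted p = 0.0859), with 0 of 18 genes passing and 2 higher when adjusted over the list alone. TPM2 was at 1.00 ± 0.25 (adjusted p = 0.0611) and ACTA2 at 0.85 ± 0.25 (adjusted p = 0.102). With 1 array left out the median of this list ran from 0.08 to 0.31, and it passed without large array 2 (0.25, adjusted p = 0.0248) and without small array 1 (0.20, adjusted p = 0.00953).

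Cell cycle lists did not pass. The G1/S list had a median of 0.02 (adjusted p = 0.566), with 0 of 24 genes passing, GINS2 at 0.43 ± 0.13 SE and CDT1 at 0.62 ± 0.22. The G2/M list had a median of 0.10 (adjusted p = 0.34), and of 30 genes the kinetochore protein gene CENPF was lower (-0.86 ± 0.14, adjusted p = 0.0089), with 4 higher and 4 lower when adjusted over the list alone. Cyclins and CDK inhibitors had a median of -0.12 (adjusted p = 0.598), with CCND2 at -0.64 ± 0.24 and CDKN1B at 0.29 ± 0.14, and apoptosis regulators had a median of 0.10 (adjusted p = 0.159), with XIAP at -0.56 ± 0.19 and BAD at 0.78 ± 0.27. With 1 array left out, the G1/S median ran from -0.049 to 0.076 and the G2/M median from 0.052 to 0.15. Cyclins and CDK inhibitors then ran from -0.183 to 0.015 and apoptosis regulators from 0.089 to 0.221.

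Among growth and metabolism lists, the cytosolic ribosomal proteins had a median of 0.03 (adjusted p = 0.0859), and of 42 genes RPL19 was higher (0.59 ± 0.14 SE, adjusted p = 0.0424). Medians and adjusted p were 0.03 and 0.513 for ribosome biogenesis, 0.07 and 0.0914 for the proteasome, 0.04 and 0.15 for the nuclear-encoded respiratory chain, and -0.03 and 0.695 for aminoacyl-tRNA synthetases and the amino acid response. For cholesterol biosynthesis they were -0.16 and 0.1, and of 17 genes 2 were lower, squalene epoxidase SQLE (-1.06 ± 0.23, adjusted p = 0.0314) and DHCR7 (-0.92 ± 0.21, adjusted p = 0.0402), and 3 when adjusted over the list alone. Oxidative stress genes had a median of 0.11 (adjusted p = 0.0859), of which sulfiredoxin, SRXN1, was higher (0.77 ± 0.17, adjusted p = 0.0383), with 3 higher and 1 lower when adjusted over the list alone. The medians and adjusted p were -0.01 and 0.69 for heat shock genes, -0.07 and 0.234 for hypoxia genes, -0.02 and 0.949 for immediate early genes and -0.14 and 0.34 for interferon response genes. CRYAB, a small heat shock protein, was at 1.67 ± 0.40 (adjusted p = 0.0511) and HLA-B at -1.12 ± 0.33 (adjusted p = 0.106). Lists in this group that passed with 1 array left out were the ribosomal proteins without large array 1 (0.05, adjusted p = 0.0209) or small array 3 (0.06, adjusted p = 0.0087), and the respiratory chain without the same arrays (0.12, adjusted p = 0.0209, and 0.17, adjusted p = 0.000238). The proteasome passed without large array 2 (0.15, adjusted p = 0.0164) or small array 3 (0.08, adjusted p = 0.0236), oxidative stress without large array 2 (0.16, adjusted p = 0.0449) and cholesterol biosynthesis without large array 3 (-0.12, adjusted p = 0.0451).

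Signalling, chromatin and RNA lists also did not pass. Medians and adjusted p were -0.07 and 0.559 for NODAL and TGF-beta targets, 0.02 and 0.949 for BMP targets, -0.14 and 0.389 for FGF and MAPK feedback, and -0.04 and 0.207 for NOTCH targets, of which NOTCH3 was lower (-1.28 ± 0.26 SE, adjusted p = 0.0263). They were 0.18 and 0.0874 for polyadenylated histones, -0.09 and 0.566 for chromatin regulators, -0.20 and 0.0546 for splicing factors, of which HNRNPA1 was lower (-0.64 ± 0.15, adjusted p = 0.041), and -0.26 and 0.128 for 6 nuclear-retained RNAs. Adjusted over the list alone, 3 NOTCH targets, 1 splicing factor, 1 nuclear-retained RNA, 1 hypoxia and 1 interferon gene were lower, 2 heat shock genes and 1 ribosomal protein gene were higher, and none passed in the other lists of these 3 groups unless given above. Splicing factors passed without large array 1, 2 or 4 or small array 3 (-0.24, -0.22, -0.19 and -0.21, adjusted p = 0.0356, 0.049, 0.0278 and 0.00573). Histones passed without large array 2 (0.24, adjusted p = 0.049) or small array 3 (0.25, adjusted p = 0.0354), and nuclear-retained RNAs without large array 4 (-0.40, adjusted p = 0.0463). The median, mean and camera direction differed in sign for extraembryonic endoderm, heat shock, the naive state and mesenchymal transition.

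A sign of RNA quality moved with the groups on 7 of the 8 arrays. This was the mean 3 prime minus 5 prime log2 difference of GAPDH and ACTB. It was between 1.95 and 2.66 on the 4 small arrays and between 1.83 and 1.89 on large arrays 2 to 4. Large array 1 had the highest value, 2.92. The means were 2.37 ± 0.30 (SD, n = 4) in small and 2.12 ± 0.53 (SD, n = 4) in large cells (exact two-sided permutation p = 0.4, and 0.8 after adjustment over 6 quality measures). For GAPDH alone, small array 2, at 0.783, lay below large array 4, at 0.828. For ACTB alone, the difference was between 2.94 and 3.86 over all 8 arrays, so it was high in both groups. The poly-A spike-in probe sets were at a mean log2 of 11.88 on small array 3 and between 7.44 and 7.64 on the other small arrays. On the large arrays they ran from 5.06 to 9.05. With large array 1 and small array 3 left out, a choice made after the data were examined, 779 genes differed, 319 higher and 460 lower. The 3 prime to 5 prime difference then separated the groups completely, with 3 small arrays between 1.95 and 2.44 and 3 large arrays between 1.83 and 1.89. With the 3 prime to 5 prime difference as a covariate, 166 differed. Pearson correlations over tested probe sets had a median of 0.928 within small, 0.931 within large and 0.918 between small and large arrays.

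**Figure D3:**
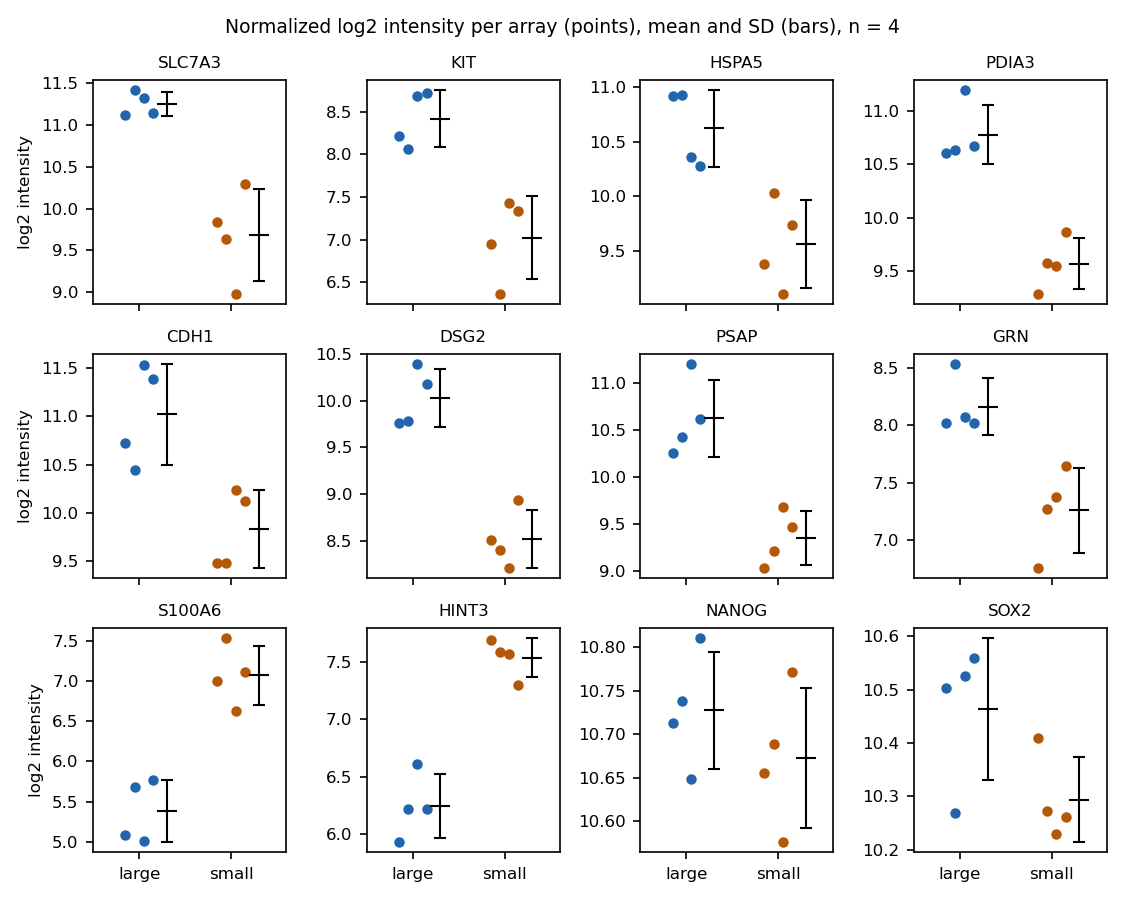
Normalized log2 intensity on the vertical axis of 12 genes per array (points), with the mean and SD of each group of 4 beside them; the vertical scales differ between panels. SLC7A3 has a mean of 11.25 in large and 9.69 in small cells, and NANOG 10.73 and 10.67.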

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

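The tests of the stem cell share, of the 3 prime to 5 prime trend and of the 4 most shifted lists were chosen only after the result was seen. The 4 lists lowest in small cells (surface and secreted, unfolded protein response, epithelial junction, lysosome and autophagy) held 85 distinct tested genes. Of these, 26 were lower and 0 higher. Their pooled median relative to all genes was -0.57. It was -0.604 with array brightness and -0.613 with the 3 prime to 5 prime difference as a covariate. The first value argues against brightness as the whole cause, although brightness differed by only -0.151 between groups, which left little to remove. A linear trend with the 3 prime to 5 prime difference is not decided, because its fit leans on large array 1. That array was at 2.92, against 1.83 to 1.89 on large arrays 2 to 4. NANOG and SOX2 argue against a lower share of stem cells in the small sort as the whole cause only if other cells lack them. That was not tested. The mean of NANOG and SOX2 relative to all genes differed by -0.14, and an exact permutation test left shifts from -0.308 to 0.003 open. These lie above the -0.495 of the 4 lists in the setting where the median of the lists lay nearest to 0. Over all 17 core pluripotency genes the share was not decided, since shifts from -0.541 to 0.404 were left open. That range reaches past -0.495, so by these genes a difference as large as the whole fall stays open. The 4 lists lay lower against these genes in small cells by a difference of -0.476 without overlap. However, 3 of 35 splits of the arrays, the real one included, set the 4 lists they shifted most in 1 direction as far from them. RNA degradation stays open too. The 3 prime to 5 prime difference was higher on all small arrays than on large arrays 2 to 4. Large array 1 had the highest such difference. It lay at 0.712 between the small (0) and other large (1) arrays over genes called lower without it. However, the quartiles over genes, 0.485 and 0.91, reached the bound of 0.5. Chance could not be excluded from the number of lists, as 12 of 35 splits of the 8 arrays gave at least the 7 lists of the real one and another gave 14, although the mean size of the 4 most shifted lists, 0.591, exceeded the highest other, 0.429, in 1 of 35 splits, the real one; the sorted size itself was not tested apart from these.

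For the counts of genes, the real split of the arrays stood apart. It gave 491 probe sets, 293 genes and 101 genes of at least 2-fold, and no other of the 35 splits gave more than 1 of any of these. As 1 of 35 is the smallest share that these splits can give, this speaks against chance but does not exclude it. The splits were run in the main setting only. On the deposited scaling, with median centring and without the variance trend the real split gave 0 genes.

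Of 292 groups of 4 arrays examined, 19 (6.51%) had an array far from the others, where chance gives about 5%. On small array 3, AIF1 was at 4.52 against 5.96 to 6.24 on the other small arrays, SEC62 at 9.67 against 9.24 to 9.29 and NODAL at 5.54 against 6.24 to 6.33. On large array 1, GLRX was at 7.98 against 7.10 to 7.23 on the other large arrays, CCDC47 at 8.65 against 9.24 to 9.28 and CTSL at 9.18 against 8.44 to 8.55. PDIA3 was at 11.19 on large array 3 against 10.61 to 10.67. GRN was at 8.53 on large array 2 against 8.02 to 8.07, and XIAP at 7.69 there against 8.02 to 8.04. CTSD was at 4.42 on small array 4 against 4.79 to 4.85, and CCN2 at 7.07 on small array 1 against 7.58 to 7.62. For lists, the mean log2 level relative to all genes was -0.65 for neural crest on large array 1 against -0.48 to -0.46, and 0.28 for fibroblast and feeder matrix on large array 2 against -0.40 to -0.32. It was -0.41 for extraembryonic endoderm on small array 4 against 0.11 to 0.14, 1.30 for surface ectoderm there against 1.16 to 1.18, and 3.75 for splicing factors on small array 3 against 3.60 to 3.61. The 3 prime minus 5 prime log2 difference on large array 1 was 1.98 for GAPDH against 0.72 to 0.83 and 3.86 for ACTB against 2.94 to 2.97. The poly-A controls on small array 3 were at 11.88 against 7.44 to 7.64.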

How the results depend on the processing

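Scaling to the 75th percentile or a trimmed mean, cyclic loess, both covariates, leaving out 2 arrays together and, for named genes, leaving out _x_at and _s_at probe sets were chosen after the data were examined. The 7 passing lists kept their direction in each setting. Some of these settings could not alter it. Those that change only the test or the variance keep the main medians. Median centring and 75th percentile scaling share the medians of the deposited scaling. Of 47 named genes called, SEC62 changed sign with the mean of its probe sets (-0.039). Without _x_at and _s_at probe sets, 33 of the 47 had a value, of which 25 stayed called and 3 changed sign, SEC62 (-0.427), PSMG4 (-0.458) and COL6A1 (0.585), since another probe set then stood for the gene. Genes, probe sets and genes of at least 2-fold called were 0, 3 and 0 on the deposited scaling, with median centring and without the variance trend (494, 1575 and 2234 genes at an unadjusted p under 0.05). They were 695, 1131 and 199 with array weights, and 779, 1150 and 278 without large array 1 and small array 3, where the 3 prime to 5 prime difference was higher on each small than on each large array. Genes and probe sets called were 550 and 877 with the brightness covariate, 166 and 299 with the 3 prime to 5 prime covariate, 190 and 290 without _x_at and _s_at probe sets (fewer were tested), and 53 and 24 at an adjusted p under 0.01. At 1.5-fold, 282 genes were called. The replicate block gave 753 genes and 1205 probe sets. Same-numbered arrays deviated together with correlations of 0.097, 0.102, 0.206 and 0.018, and 3 of the 4 numbers matched best with themselves, a hint from the data and not the design. With 1 array left out, genes ranged from 62 to 555, probe sets from 49 to 792, genes of at least 2-fold from 46 to 203, and passing lists from 7 to 11. Of the 37 lists that did not pass, 10 passed with some array left out, and the median of 18 changed sign with some array left out. Passing lists numbered 12 with median centring, 11 with 75th percentile or trimmed mean scaling, 4 with fry and 0 with an estimated correlation, where the medians of the 4 lowest lists, -0.834, -0.57, -0.559 and -0.402, and of the WNT list, -0.281, are those of the main setting. The lysosome list was at -0.61 without 2 arrays and at -0.269 with the mean of all probe sets, and passed in both. The WNT list also no longer passed with fry (-0.281) or without _x_at and _s_at probe sets (-0.231); leaving out 1 array gave -0.425 to -0.222 and leaving out 2 gave -0.492. The glycolysis list no longer passed with an estimated correlation or fry (-0.213), on the deposited scaling, with median centring or 75th percentile scaling (-0.157), with the trimmed mean (-0.156), with the 3 prime to 5 prime covariate (-0.138) and without _x_at and _s_at probe sets (-0.287); leaving out 1 array gave -0.287 to -0.155. The p53 target list no longer passed with an estimated correlation, fry or no variance trend (0.223), with array weights (0.205), without 2 arrays (0.192), on the deposited scaling (0.197), at the 60th percentile filter (0.216) or without _x_at and _s_at probe sets (0.226); leaving out 1 array gave 0.118 to 0.282. Apart from settings where fewer or other probe sets were tested, the cause of this dependence on the processing was not tested. Signal over background was not assessed here, and the authors' background correction is not given in the sources used here.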

Other observations

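The lists of gene families below were tested after the main result was seen, as was the test of very large proteins. Families of membrane and secreted proteins taken by gene symbol were lower in small cells as a class of 565 genes, with a median of -0.26 relative to all genes, 72.6% of them below the median of all genes, and 34 lower and 0 higher (camera adjusted p = 1.4e-09, and adjusted p = 0.0222 with an estimated correlation). Solute carriers outside the mitochondria had a median of -0.32 over 255 genes, with 15 lower, among them the zinc transporters SLC39A10 (-1.48), SLC39A7 (-1.24) and SLC39A14 (-0.90). TMEM genes had a median of -0.15, with 9 of 179 lower. Receptor tyrosine phosphatases had a median of -0.41, with PTPRZ1 (-1.36), PTPRK (-1.18) and PTPRF (-1.18) lower among 17. Cadherins and protocadherins had a median of -0.32, with 4 of 42 lower, and ADAM proteases -0.30, with 0 of 37 passing alone. Integrins and laminins had a median of -0.26 (adjusted p = 0.00758, and adjusted p = 0.25 with an estimated correlation), with 3 of 35 lower. The directions of these families were the same on the deposited scaling. Median centring and 75th percentile scaling shift each array by 1 constant, which cancels in a median relative to all genes. Their medians therefore could not differ from those on the deposited scaling and are no further check. Trimmed mean scaling, also 1 factor per array, was close, with a median of -0.298 for the class against -0.295 on the deposited scaling.

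Of 7 mitochondrially encoded genes, 4 were lower, ND2 (-1.49), COX2 (-1.04), ND6 (-0.93) and ND4 (-0.50), with a list median of -0.74 (adjusted p = 1.4e-09, and adjusted p = 0.0257 with an estimated correlation). Nuclear-encoded mitochondrial ribosomal proteins had a median of 0.31 over 76 genes, of which 2, MRPL41 (0.89) and MRPL9 (0.57), were called, both higher (list adjusted p = 8.87e-13, and adjusted p = 0.127 with an estimated correlation). Mitochondrial carriers (0.03, adjusted p = 0.436), zinc finger genes (0.04, adjusted p = 0.255), ubiquitin-specific proteases (-0.07, adjusted p = 0.435) and kinesins and dyneins (0.05, adjusted p = 0.444) did not pass.

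A hypothesis is that genes of proteins made at the endoplasmic reticulum are lower in small cells as a class. The median of the symbol families, -0.262, has the direction it predicts. These families share genes with the 4 lowest lists, so this is no independent support. Long genes as the whole cause are argued against, because the 4 lowest lists kept a median of -0.565 after removing the trend on genomic span and mean level; the length of the transcripts was not tested. Transcripts of very large cytosolic or nuclear proteins were also lower, with a median of -0.483 over 54 genes and 12 lower, among them DYNC1H1 (-1.38), VPS13C (-1.37) and SPTBN1 (-1.34). Protein size or transcript length may therefore account for part of the pattern and stays open beside the endoplasmic reticulum. RNA quality was not separated from these and also stays open. The 3 prime to 5 prime difference was higher on every small array than on large arrays 2 to 4.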
